A study of Arabidopsis thaliana with 48 samples.

How the data were processed

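The series covers Arabidopsis thaliana seedlings, grown for 12 days under 16 h of light and 8 h of dark per the labels' protocols. It holds 48 samples, of which 3 wild-type (WT) and 3 acc1-5 libraries are RNA-seq libraries made from mRNA, and 42 are chromatin immunoprecipitation (ChIP) or input libraries. The 38 ChIP libraries cover 9 histone marks in WT and acc1-5. They cover H3K27ac alone in a line that carries acc1-5 with an estradiol-inducible construct against ACLA-1, which the titles give as induced or mock. The labels' treatment text, a spray of 20 µM estradiol or solvent for 24 h, is repeated for all samples and does not say whether the seedlings for RNA were sprayed. The ChIP and input libraries were not analysed here. The processed tables used here are a table of transcript levels and a table of the authors' comparison of acc1-5 with WT.

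Reads were processed with TopHat 1.4.0, Cufflinks 2.1.1 and Cuffdiff 2.1.1 on the TAIR10 build, per the submitters' processing notes, which also name Bowtie. The authors deposited transcript levels as FPKM, fragments scaled to transcript length and to the number of mapped fragments, with 1 value per genotype and a lower and upper confidence bound for each value. The confidence level of these bounds and the way the libraries of a genotype were combined are not given in the sources used here. The authors' log2 fold change is the log2 of the acc1-5 FPKM over the WT FPKM, so a positive value means a higher level in acc1-5. Per the file headers, the authors' comparison also holds a p-value and a q-value for each transcript, and a status that marks which transcripts their program tested. The authors' test statistic, deposited as a score with no fixed range, was not used here. Columns of the mutant carry the name ACC1 and were read as acc1-5, the only mutant with RNA libraries in the labels.

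The tables list 42818 transcripts of 33553 genes. The authors' program tested 25307 of these transcripts, gave no test for 16851 and marked 660 as having too few data. None of the 278 transcripts of the organelle genomes was tested. A transcript was called changed where it was tested and the authors' q-value was under 0.05. The smallest p-value their program gives is 5e-05, held by 1697 tested transcripts, so their order by p cannot be told. Depth per library is unknown: low FPKM values are not whole multiples of a common step (10.3% of low WT values and 11.4% of low acc1-5 values lay within 5% of one), so reads could not be recovered and no count test was run.

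The design fixed before the data were examined planned limma on values of single libraries, and the authors' q-values if the tables held only 1 value per genotype. The second case applied, so limma, a replicate block, leaving out single libraries and other splits of the libraries could not be run. A difference between genotypes therefore has no replicate check here beyond the authors' own test, and the labels do not say whether the libraries came from separately grown seedlings.

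For lists of genes, a gene was represented by its transcript with the highest mean FPKM, which left 20509 tested genes. The 27 lists were fixed before the data were examined. They are cytosolic acetyl-CoA supply and carboxylation, fatty acid elongation and cuticular wax, plastid fatty acid synthesis, mevalonate and sterol synthesis, flavonoid and anthocyanin synthesis, glucosinolate synthesis, beta-oxidation and the glyoxylate cycle, histone acetyltransferases, histone deacetylases, Polycomb repressive complex 2, Polycomb-regulated developmental genes, light harvesting and Rubisco small subunit, salicylic acid and immune response, jasmonate and ethylene response, abscisic acid, cold and drought response, heat shock and protein folding, mitotic cell cycle, auxin response, cytokinin response, iron deficiency response, phosphate starvation response, senescence, circadian clock, low oxygen and touch response, root hair markers, root endodermis and suberin markers, and stomatal lineage and guard cell markers. Each list was tested in each direction against all other tested genes with a two-sided Fisher's exact test, and the 54 tests were adjusted by the Benjamini-Hochberg method. The percentile of a list's median log2 fold change was taken among 10000 random lists of the same size, matched on deciles of mean FPKM. Intervals of medians are 95% bootstrap intervals over genes from 10000 draws. Genes are not independent replicates, so these tests and intervals describe these libraries.

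Lists of other root markers (stele, root cap, root tip, and cortex and uptake), of seed storage proteins, and of seed oil body and late embryogenesis genes were written after the tables had been examined and are used only in the closing section.

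Genes named in the text were chosen by a rule fixed before the data were examined. It takes ACC1 and the other members of the acetyl-CoA list, and the 8 largest rises and 8 largest falls on the log2 scale among called genes with a symbol, a mean FPKM of at least 1 and an FPKM above 0 in both genotypes. In each list with 3 or more called members it takes the 4 with the largest absolute log2 change, in each list with 1 or 2 called members it takes those, and in a list with none called it takes the 2 members with the highest mean FPKM. Among genes called with an FPKM of 0 in 1 genotype, it takes the 2 with the highest FPKM in the other. Named genes of lists that are only counted were left out in places, and in the Results a gene named outside the rule is said to be so. Genes named in the additional observations at the end were not chosen by this rule.

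Symbols were taken by locus identifier from the RefSeq gene table of assembly TAIR10.1, used for names and neighbours only; it holds 32806 of the gene identifiers. Coordinates are those of the deposited tables on TAIR10, written from 1: 38.7% of the deposited starts plus 1 equal the RefSeq gene start, against 0.405% of the starts as given. The library kit for RNA is not stated to mark strand, so overlapping and antisense genes, and near-identical copies, share reads and are uncertain.

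Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and statsmodels 0.14.6, and plots were drawn with Matplotlib 3.10.9. The list test was tested on simulated data for acc1-5 against WT over 20509 genes: 10 of 10 lists with planted changes were recovered, with 0 calls among 70 lists and directions without change. Most members of each planted list were called higher, whereas 25% of the fatty acid elongation and wax list were called lower. Members were drawn at random, so the simulation does not cover smaller shares or lists of genes that change together. The alternatives tried were a q-value under 0.01, an absolute log2 fold change of at least 1, an FPKM of at least 1, adjustment over those transcripts again, Bonferroni adjustment, confidence intervals that do not overlap, centring on the median, pseudocounts of 0.1 and 1, 1 transcript per gene, any called transcript of a gene, lists adjusted alone, and lists without members whose locus holds another gene.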

Results

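The RNA data compared 12-day-old acc1-5 seedlings with WT seedlings of the Col-0 ecotype. The labels repeat the same treatment text for all samples, so whether the RNA seedlings were sprayed with solvent or estradiol is not clear from them. ACC1 encodes the cytosolic acetyl-CoA carboxylase, which converts acetyl-CoA to malonyl-CoA, and acc1-5 is an allele of this gene. The series title concerns cytosolic acetyl-CoA and acetylation of histones, and the RNA comparison asks which transcripts differ in level between the genotypes. The labels give 3 RNA libraries per genotype, and the tables give 1 FPKM value per genotype with the authors' confidence bounds, so every value below is the authors' estimate, without a spread between libraries. Sequencing depth is unknown. The median half-width of the WT bounds was 41.6% of the FPKM among tested transcripts with a WT FPKM of at least 1.

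ACC1 itself (AT1G36160, chromosome 1, 13533411 to 13544009 on TAIR10) stood at nearly the same level in both genotypes. In the authors' deposited table, its main transcript had 33.1 FPKM in WT (bounds 21.6 to 44.7) and 33.4 in acc1-5 (21.4 to 45.4), a log2 fold change of 0.01 with q = 0.991. A minor ACC1 transcript had 1.39 FPKM in WT and 2.37 in acc1-5 in the authors' deposited table (q = 0.891). The labels do not say whether acc1-5 alters the transcript, so the ACC1 level says little about whether the libraries carry the right genotype. The list of cytosolic acetyl-CoA supply and carboxylation, which includes ACC1 itself and ACC2, had close values too. Of its tested members, 0 of 8 were called (0 adjusted over the list alone), with a median log2 fold change of 0.07 (-0.11 to 0.26). The plastid-targeted carboxylase gene ACC2 had 1.97 FPKM in WT and 2.56 in acc1-5 (q = 0.280) in the authors' deposited table, and ACLB-2, a subunit gene of ATP-citrate lyase, 35.1 and 37.4 (q = 0.865). For ACLA-1, ACLA-2, ACLA-3, ACLB-1, ACS and ACN1 the log2 fold changes in the authors' deposited table lay between -0.13 and 0.26, with ACLA-1 not tested for too few data.

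Many other transcripts differed between acc1-5 and WT. Of 25307 tested transcripts, 4130 (16.3%) were called, 2251 higher and 1879 lower in acc1-5, from 4105 genes, in the authors' deposited table. Larger changes were mostly rises: 1620 transcripts were at least 2-fold higher and 671 at least 2-fold lower, and with that limit 70.7% of the calls were rises, against 54.5% of all calls. The median log2 fold change of tested transcripts was -0.01, with an interquartile range of -0.34 to 0.32. Detection depended on level, since of 4 equal groups by expression the highest had 24.4% of its transcripts called and the lowest 11.5%, and the smallest absolute log2 change called was 0.48 and 0.83 in these groups. No call passes a Bonferroni adjustment, because the smallest p-value of the authors' program is too large for that number of tests.

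**Figure D1:**
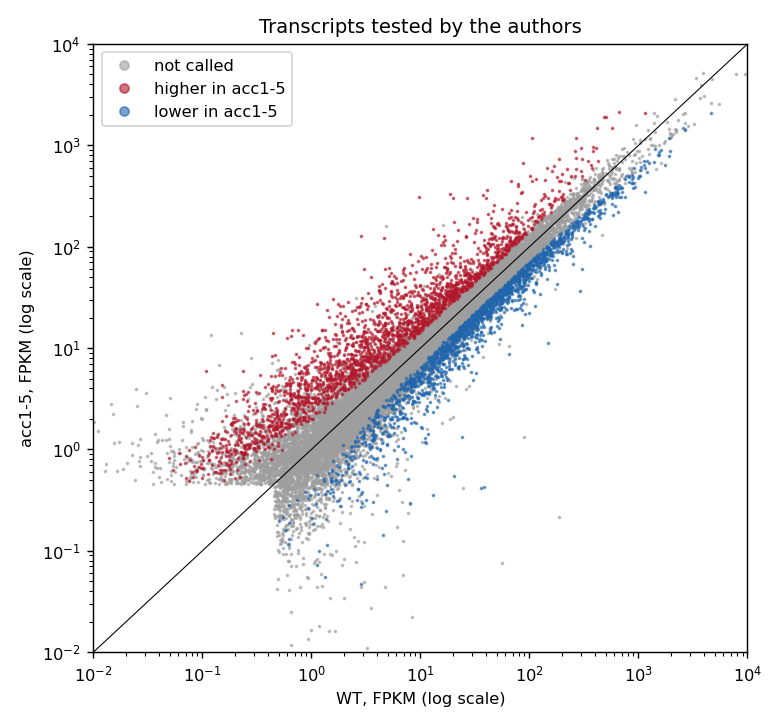
Transcript levels of acc1-5 (vertical axis) against WT (horizontal axis) in FPKM on log scales, for transcripts tested by the authors with an FPKM above 0 in both; colours mark transcripts called higher (red), lower (blue) or not called (grey), and the line marks equal levels; a few transcripts under the axis minimum are not drawn. Most points lie along the line, and of the called transcripts 1620 were at least 2-fold higher and 671 at least 2-fold lower in acc1-5.

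The largest rises and falls, ranked among called genes with a symbol, a mean FPKM of at least 1 and an FPKM above 0 in both genotypes, were spread over genes of different kinds. scpl30 (AT4G15100), a serine carboxypeptidase-like gene, rose from 0.107 to 5.95 FPKM (log2 5.80, q = 0.00690), and NATA1 (AT2G39030, chromosome 2, 16298227 to 16299202), an acetyltransferase gene of ornithine metabolism, from 2.83 (1.16 to 4.46) to 127 (61.9 to 191), in the authors' deposited table. IPS1 (AT3G09922, chromosome 3, 3050989 to 3051530), a non-coding RNA that binds a phosphate-responsive microRNA, rose from 9.80 (3.51 to 13.8) to 310.4 FPKM (145 to 343) in the authors' deposited table. Further rises there were of ADPG1, a polygalacturonase gene (log2 4.84 in the authors' deposited table), MSRB7, a methionine sulfoxide reductase gene (4.73), TPS04, a terpene synthase gene (4.65), DIR5, a dirigent protein gene (4.58), and JAZ8, a repressor of jasmonate signalling (4.32). Among the genes so ranked, the largest fall in the authors' deposited table was that of PCC1 (AT3G22231, chromosome 3, 7845823 to 7846605), a small defence-related gene, from 38.2 (14.7 to 51.1) to 0.422 FPKM (0 to 0.831), with q = 0.00528. SEP2 (AT3G02310, chromosome 3, 464279 to 467074), a floral MADS-box gene, fell from 4.57 to 0.141 FPKM in the authors' deposited table (log2 -5.01, q = 0.00443). The next falls among the ranked genes in the authors' deposited table were of PCR1 (log2 -3.71), AP1 (-3.48), NAC090 (-3.38), the receptor-like protein gene RLP42 (-3.33), MSRB4 (-3.29) and the zinc finger gene ZFP8 (-3.23). For 39 called transcripts the level was listed as 0 in 1 genotype, 27 in WT and 12 in acc1-5. Those highest in acc1-5 were AT4G19239, at 17.9 FPKM in the authors' deposited table, an estimate outside its own bounds of 2.43 to 14.6, and its neighbour AT4G19240. AT4G07825 and AT5G52160 were the highest in WT among those listed at 0 in acc1-5.

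Root hair and root endodermis markers were higher in acc1-5 seedlings. All 5 tested root hair markers rose (5 adjusted over the list alone), with a median log2 fold change of 2.95 (2.52 to 3.81), and 11 of 12 tested markers of the endodermis and its suberin rose (12 adjusted over the list alone), with a median of 1.94 (1.84 to 2.14). The expansin gene EXPA7 rose by 3.81 on the log2 scale from 1.44 FPKM (0.526 to 2.33), and the cell wall protein gene PRP3 from 5.76 (2.97 to 8.54) to 51.5 (30.5 to 71.9), in the authors' deposited table. Among endodermal genes, the suberin hydroxylase gene CYP86A1 rose from 3.01 (1.58 to 4.43) to 14.8 FPKM and the regulator MYB36 from 1.22 to 5.52 in the authors' deposited table, and CYP86B1 and FAR5 rose as well. Calls of rises were more frequent in both lists than among other genes (Fisher's exact test, adjusted p = 1.66e-04 for root hairs and 4.92e-09 for the endodermis).

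Every gene of the phosphate starvation list rose. All 13 tested members were called higher (13 adjusted over the list alone), with a median log2 fold change of 2.39 (1.47 to 3.17), a 5.25-fold rise. The phosphatase gene PS2 rose from 26.9 (15.7 to 38.0) to 306 FPKM (183 to 420.2), the galactolipid synthase gene MGD3 from 5.15 (2.80 to 7.49) to 51.4 (35.4 to 67.5), and the phosphate transporter gene PHT1;4 from 14.6 (9.33 to 19.7) to 131 (85.8 to 176), in the authors' deposited table. Rises were more frequent than among other genes (Fisher's exact test, adjusted p = 8.46e-12). Root hair and endodermis markers, with medians of 2.95 and 1.94, rose in the same comparison.

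Rises were frequent in the jasmonate and ethylene response list. Of 24 tested members, 18 rose, 1 fell and 5 were not called (19 rose and 1 fell adjusted over the list alone), and the list median was 2.64-fold higher in acc1-5 (0.85 to 1.87 on the log2 scale). The tyrosine aminotransferase gene TAT3 rose from 8.10 (4.75 to 11.4) to 83.8 FPKM (44.5 to 123), LOX2, a lipoxygenase gene of jasmonate synthesis, from 41.1 (28.4 to 53.7) to 362 (189 to 535), and AOC1, an allene oxide cyclase gene, from 40.3 to 305, in the authors' deposited table. AOC1 has near-identical copies, as have several defensin genes of this list, so levels of single copies are uncertain. Among the same libraries' root markers, those of root hairs and the endodermis had medians of 2.95 and 1.94. The member of the list that fell, named after its values were seen, was VSP1, a vegetative storage protein gene, from 83.1 to 53.9 FPKM in the authors' deposited table (q = 0.0114). Rises were more frequent in this list than among other genes (Fisher's exact test, adjusted p = 8.46e-12).

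Falls were more frequent than rises in the salicylic acid and immune list, although 13 of 24 tested members were not called. In that list 8 fell and 3 rose (9 and 3 adjusted over the list alone). In the authors' deposited table, the glucanase gene PR2 fell from 72.4 (45.5 to 97.6) to 23.9 FPKM (14.6 to 32.9) and NIMIN1, whose product binds the salicylic acid co-activator NPR1, from 6.75 to 2.29. The 3 that rose were CYP71A13, PAD3 and CYP71A12 (the last named after its values were seen), which encode enzymes of the antimicrobial compound camalexin. CYP71A13 rose from 11.3 (6.89 to 15.7) to 79.3 FPKM (39.2 to 119) and PAD3 from 12.2 (7.64 to 16.7) to 56.0 (29.5 to 82.2), in the authors' deposited table. Falls were more frequent than among other genes (Fisher's exact test, adjusted p = 0.00519), while the median of -0.36 had an interval of -0.67 to 0.16. Beside these changes, root hair and endodermis markers had medians of 2.95 and 1.94.

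Low-oxygen genes rose and touch genes fell. Of 12 tested members of their joint list, 9 rose and 3 fell (9 and 3 adjusted over the list alone); the 3 were the touch genes TCH2, TCH3 and TCH4, named after their values were seen, and the 9 were the low-oxygen genes. The pyruvate decarboxylase gene PDC1 rose by 2.44 on the log2 scale from 5.89 FPKM (3.54 to 8.22), PCO2, a plant cysteine oxidase gene, rose by 1.84, and the transcription factor gene HRE2 rose from 0.260 to 2.41, in the authors' deposited table. The alcohol dehydrogenase gene ADH1 rose from 16.5 to 62.9 FPKM in the authors' deposited table, at a locus it shares with another gene. Rises were more frequent than among other genes (Fisher's exact test, adjusted p = 4.68e-06), and the median of 1.47 had an interval of -0.09 to 1.88, with members going both ways. Alongside, root hair and endodermis markers had medians of 2.95 and 1.94.

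Rises were frequent among flavonoid and anthocyanin genes and among heat shock genes. Of 23 tested flavonoid and anthocyanin genes, 9 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 0.95 (0.47 to 1.27; Fisher's exact test, adjusted p = 0.00283). The regulator PAP1 rose from 0.425 to 2.46 FPKM, the anthocyanin glycosyltransferase gene UF3GT by 2.45 on the log2 scale from 0.642, the reductase gene DFR from 5.39 (2.84 to 7.94) to 22.6, and TT19, a glutathione transferase gene, from 6.07 to 22.4, in the authors' deposited table. Of 14 tested heat shock genes, 6 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 1.00 (0.62 to 2.44; adjusted p = 0.0125). Small heat shock protein genes led that list in the authors' deposited table: HSP17.6A rose from 0.709 to 6.30 FPKM, HSP17.6II from 0.468 to 4.14, HSP18.2 from 4.97 to 19.7 and HSP17.8 from 2.91 to 6.34. With q under 0.01, 4 heat shock genes were called and the list no longer stood out (adjusted p = 0.0924). Both lists rose in libraries where root hair and endodermis markers had medians of 2.95 and 1.94.

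Falls were frequent in the list of Polycomb-regulated developmental genes. The falls named here, and that of SEP2 above, are of genes of flowers or flowering. Histone marks were not analysed, so these falls do not show a change in Polycomb regulation. Whether the genotypes had reached the same developmental stage was not tested. Of 18 tested members of this list, 8 fell, 0 rose and 10 were not called (11 fell and 0 rose adjusted over the list alone), with a median log2 fold change of -1.57 (-1.80 to -0.15), and of -0.83 with a pseudocount of 1. The floral identity gene AP1 fell from 4.93 (2.51 to 7.34) to 0.442 FPKM (0.111 to 0.738), AP3, which specifies petals and stamens, to 1.70 (0.524 to 2.84; log2 -1.87), and FT, the mobile flowering signal, from 15.0 (7.84 to 21.3) to 4.53 (1.91 to 7.10), in the authors' deposited table. Falls were more frequent than among other genes (Fisher's exact test, adjusted p = 6.50e-04). The meristem genes STM and KNAT1, named after their values were seen, had q-values of 0.909 and 0.369 in the authors' deposited table. The root hair and endodermis markers of these libraries had medians of 2.95 and 1.94. None of 6 tested subunit genes of Polycomb repressive complex 2 was called (0 adjusted over the list alone); SWN and MSI1 had log2 fold changes of 0.01 and 0.22 in the authors' deposited table, and MSI1 shares its locus with another gene.

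Falls were also frequent among auxin response genes and, less firmly, among genes of fatty acid elongation and wax. Of 13 tested auxin genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone), with a median log2 fold change of -0.73 (-0.85 to -0.04; Fisher's exact test, adjusted p = 4.63e-04). IAA29, an Aux/IAA repressor gene, fell from 10.2 (5.22 to 15.1) to 1.66 FPKM (0.596 to 2.70), IAA1 from 20.5 to 10.8, IAA3 from 36.2 to 19.1 and IAA2 from 195 to 108, in the authors' deposited table. Grouped by symbol stem after the tables had been examined, 6 of 20 IAA genes fell and 3 rose, and 0 of 15 SAUR genes fell and 1 rose. Falls of the IAA stem did not pass adjustment (Fisher's exact test, p = 0.00693, adjusted p = 0.0687). Stems were adjusted over 228 tests, more than the fixed lists, so their adjusted values cannot be compared directly with those of the lists. Median log2 fold changes were negative in both stems, at -0.20 for IAA and -0.40 for SAUR genes. Of 32 tested genes of fatty acid elongation, which uses malonyl-CoA, and of cuticular wax, 8 fell, 0 rose and 24 were not called (11 fell and 1 rose adjusted over the list alone), with a median of -0.25 (-0.50 to -0.01; adjusted p = 0.0316). In the authors' deposited table, the wax ester synthase gene WSD1 fell from 5.03 (2.85 to 7.19) to 1.36 FPKM, and the ketoacyl-CoA synthase genes KCS16 and KCS8 from 25.1 to 10.6 and from 125 to 62.2, with the reductase gene CER4 falling from 2.53 to 1.22. With q under 0.01, 4 genes of this list were called and it no longer stood out (adjusted p = 0.392). By symbol stem, 3 of 17 KCS genes fell and 0 rose, with a median of -0.09, and their falls did not pass (Fisher's exact test, adjusted p = 0.792). In the same libraries, markers of root hairs and of the root endodermis had medians of 2.95 and 1.94.

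Genes of light harvesting and the Rubisco small subunit had lower levels, although few passed the test. Of 22 tested members, 21 had a lower level in acc1-5, and 5 of them fell (5 adjusted over the list alone), among them LHCB2.3, LHCB1.1, RBCS1B and LHCB4.2. LHCB2.3 fell from 161 (90.5 to 220) to 74.5 FPKM (42.1 to 107) and LHCB1.1 from 1004 (451 to 1556) to 495 (251 to 736), in the authors' deposited table. Falls made up 22.7% of the list and 9.04% of all tested genes, which did not pass the adjusted test (Fisher's exact test, p = 0.0432, adjusted p = 0.157). The list median of -0.69 (-0.90 to -0.63) lay below those of all 10000 random lists matched on deciles of mean FPKM. Those random lists hold genes drawn singly, so members that change together or share reads can give an extreme percentile. Copies of these genes are near-identical and LHCB4.2 shares its locus with another gene, so single levels are uncertain. Root hair and endodermis markers, with medians of 2.95 and 1.94, were higher in these acc1-5 libraries.

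The remaining lists did not pass the test in either direction, with 0.0669 as their lowest adjusted p. Of 25 tested glucosinolate genes, 7 rose and 1 fell (8 and 3 adjusted over the list alone; adjusted p = 0.0669 for rises); their median was 0.30 and their mean -0.12, of opposite sign. CYP79F2, CYP79B2 and the regulator MYB34 rose by 1.18, 1.01 and 1.12 on the log2 scale, and MYB29, a regulator of aliphatic glucosinolates, fell by 2.22, in the authors' deposited table. Of 13 clock genes, 4 fell (5 adjusted over the list alone), RVE1, RVE8, RVE4 and CCA1, with log2 fold changes of -1.50, -1.38, -0.95 and -0.94 in the authors' deposited table (adjusted p = 0.102 for falls). With q under 0.01, 4 clock genes were called lower and that list passed the test (adjusted p = 0.0268). Of 10 stomatal genes 3 fell (3 adjusted over the list alone), of 21 mitotic genes 3 fell (3), of 11 cytokinin genes 3 rose and 1 fell (3 and 1), of 10 senescence genes 2 rose and 3 fell (2 and 3), and of 24 abscisic acid, cold and drought genes 5 rose and 3 fell (5 and 3). Of 17 genes of beta-oxidation and the glyoxylate cycle 4 rose and 1 fell (4 and 1 adjusted over the list alone), and the isocitrate lyase gene ICL rose from 2.60 to 19.2 FPKM (11.5 to 26.9) in the authors' deposited table. Of 10 iron deficiency genes, FRD3 and F6H1 rose (2 adjusted over the list alone), of 24 mevalonate and sterol genes PMK rose (1), and of 17 plastid fatty acid genes FATA1 rose and FATA2 fell (0 and 0). F6H1 and PMK share their loci with other genes. Medians of some of these lists lay toward an end of the 10000 random lists matched on deciles of mean FPKM. The percentiles were 0.06 for stomatal genes (median -0.54, 9 of 10 members lower), 1.71 for clock genes, 98.0 for iron deficiency, 98.8 for cytokinin, 99.8 for mevalonate and sterol (median 0.23, 18 of 24 members higher) and 99.9 for glucosinolate genes. None of 10 tested histone acetyltransferase genes was called (0 adjusted over the list alone), and HAC1 and HAM1 had log2 fold changes of -0.11 and -0.22 in the authors' deposited table, with HAM1 at a shared locus. Of 15 tested histone deacetylase genes, HDT4 rose and HDA14 fell (1 and 1 adjusted over the list alone), with log2 fold changes of 0.82 and -0.74 in the authors' deposited table.

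**Figure D2:**
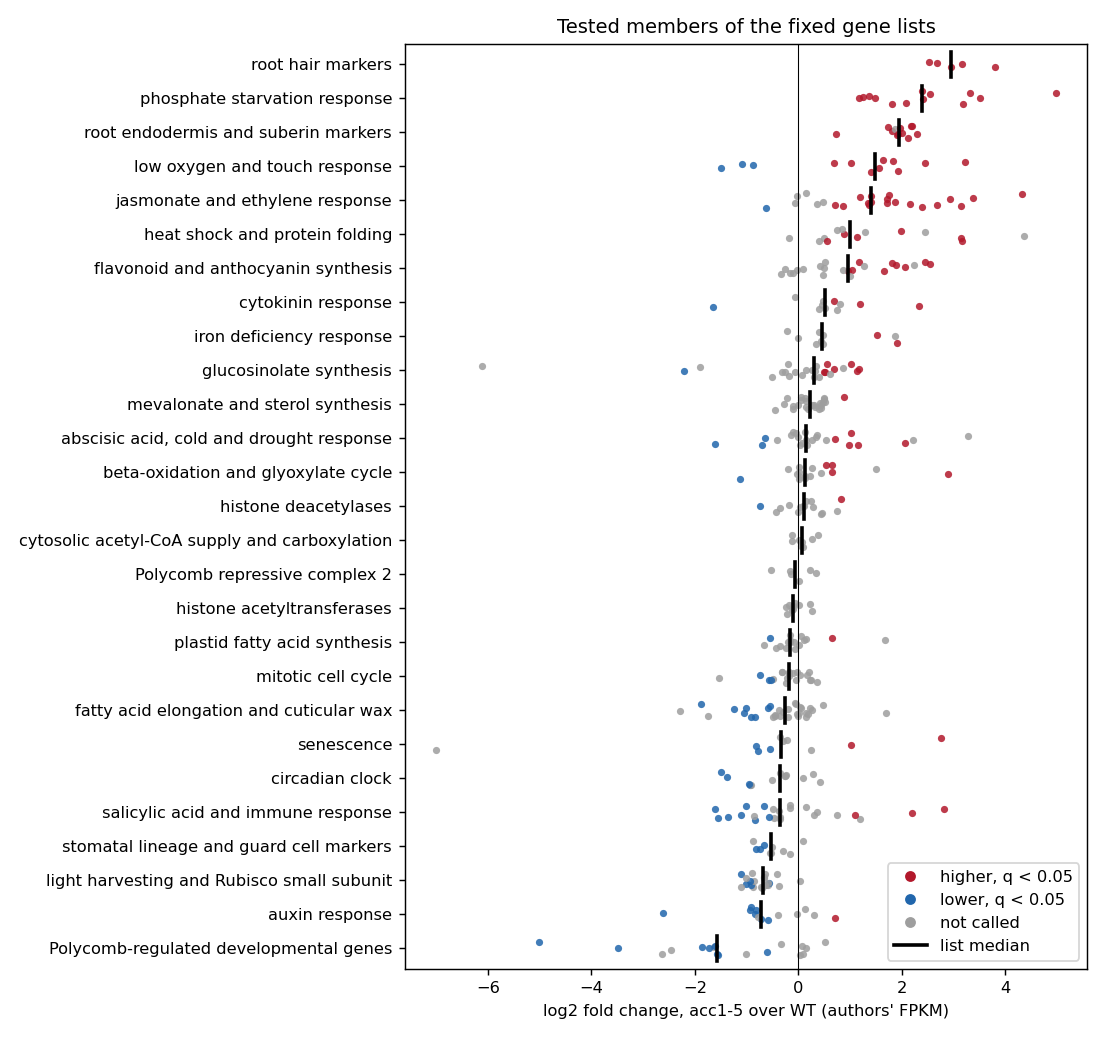
Log2 fold change of acc1-5 over WT (horizontal axis, authors' FPKM) for each tested member of the 27 fixed gene lists with an FPKM above 0 in both genotypes; red and blue points were called higher and lower at q under 0.05, grey points were not called, and black bars are list medians. Root hair markers (median 2.95) and phosphate starvation genes (2.39) stand at the top, and Polycomb-regulated developmental genes (-1.57) at the bottom.

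**Figure D3:**
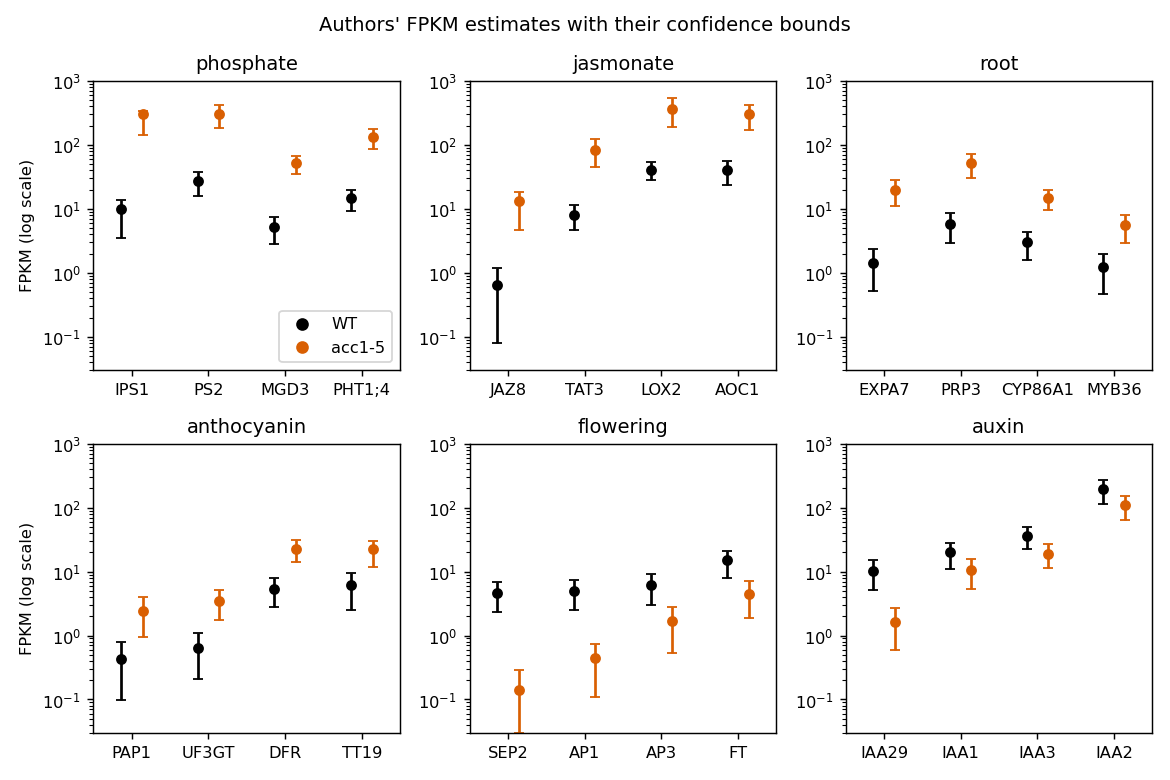
FPKM on a log scale for 24 genes in 6 groups, WT in black and acc1-5 in orange; points are the authors' estimates and bars their confidence bounds, with bounds under the axis minimum drawn to it. IPS1 stands at 9.80 in WT and 310.4 in acc1-5, and AP1 at 4.93 and 0.442.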

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

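All cut-offs and tests in this part were chosen after the values had been seen. Outside the tested transcripts, 7 untested transcripts with a mean FPKM of at least 10 were more than 2-fold higher in acc1-5, and 10 were more than 2-fold lower. What drew attention to them is a large difference in transcripts that the comparison leaves out. Of the 7, 5 are shorter than 150 bases, and 2 were marked as having too few data. AT5G13420, of 1705 bases, was one of the latter, with 54.7 FPKM in WT (34.6 to 74.9) and 115 in acc1-5 (74.3 to 156) in the authors' deposited table. The short AT3G25233, of 93 bases, was listed at 0 in WT and at 1322 in acc1-5 in the authors' deposited table, with bounds of 0 to 3.41 that do not hold the estimate. On the lower side, 7 of the 10 were shorter than 150 bases and 3 had too few data. There AT2G24592, also of 93 bases, was listed at 1488 FPKM in WT and at 0 in acc1-5 in the authors' deposited table. Its WT bounds of 0 to 3.41 do not hold the estimate either.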

How the results depend on the processing

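The alternative without members at shared loci was added after the tables had been examined, and the others were fixed before. Among all calls, the 4130 became 2291 with an absolute log2 fold change of at least 1, 1318 where the bounds of the genotypes do not overlap, and 0 with Bonferroni. Rises numbered 1003 where the bounds do not overlap and 0 with Bonferroni. Falls numbered 1174 at q under 0.01, 671 with an absolute log2 fold change of at least 1, 315 where the bounds do not overlap and 0 with Bonferroni. The Bonferroni result follows from its construction, since the smallest p-value, 5e-05, is too large for 25307 tests. The log2 limit removes small changes by its construction. Whether the calls removed by the stricter q-value and by the bounds were also small changes was not tested. The share of rises went from 54.5% to 70.7% with the log2 limit and 76.1% with bounds that do not overlap. At q under 0.01, 4 wax genes were called lower and 4 heat shock genes higher, and neither list stood out; the cause was not tested beyond the lower number of calls. Centring and pseudocounts could not change the sign of a call, since the median shift was -0.01 and the smallest absolute log2 change called 0.48. A pseudocount of 1 lowered the median of root hair markers from 2.95 to 2.36 and of endodermis markers from 1.94 to 1.42, and moved that of Polycomb-regulated genes from -1.57 to -0.83, as it does for low transcripts. Without members at shared loci, the 11 lists that stood out kept most of their calls. Calls went from 9 to 7 for flavonoid genes, 13 to 12 for phosphate, 9 to 8 for low oxygen and touch, and 11 to 10 for endodermis markers. The other lists lost none. No paired analysis was possible because the tables hold 1 value per genotype; for the same reason limma, leaving out single libraries and other splits of the libraries were not run. Depth is unknown, and small changes of low transcripts could not be called, the smallest absolute log2 change called being 0.83 in the lowest of 4 equal groups by expression.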

Other observations

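Genes in this paragraph were grouped after the tables had been examined, by 114 symbol stems with at least 10 tested genes, in 228 Fisher's exact tests. A stem is not a family and can hold unrelated genes: CYP covers cytochrome P450 genes and some cyclophilin genes, CRK covers receptor kinase and calcium-dependent-protein-kinase-related genes, and PAP and RPL are mixed as well. Of 26 GSTU genes (tau glutathione transferases), 14 rose and 1 fell, of 36 ABCG transporter genes 14 rose and 4 fell, and of 52 UGT glycosyltransferase genes 17 rose and 1 fell. Among 162 genes with the CYP stem, 51 rose and 25 fell (adjusted p = 2.34e-10 for rises and 0.0755 for falls), with a median log2 fold change of 0.26. GSTU6 rose from 3.16 to 27.5 FPKM and ABCG40 from 7.45 to 26.8, in the authors' deposited table. Of 17 EXPA (alpha-expansin) genes 8 rose and 1 fell, of 26 XTH (xyloglucan endotransglucosylase) genes 10 rose and 3 fell, and of 60 WRKY genes 18 rose and 4 fell. The stems PTAC, HCF and CRR, named for plastid transcription and photosynthetic complexes, had 9 of 14, 7 of 12 and 5 of 10 genes lower and 0 higher, in libraries where root hair and endodermis markers had medians of 2.95 and 1.94. HCF173 fell from 87.8 to 44.8 FPKM and PTAC16 from 340.2 to 187, in the authors' deposited table. Of 36 genes with the CRK stem 11 fell and 4 rose, of 49 RLP genes 13 fell and 3 rose, and of 15 genes with the TCP stem 6 fell and 0 rose. In all, 19 of the 228 tests stood out after adjustment, and the others were of JAZ, BGLU, MYB, ABCC, PAP and RPL stems.

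The rise of root hair and endodermis markers was weighed against technical explanations; the test on other root markers was written before its values were seen, and the test of scaling after. No shift common to the tested transcripts was seen, as their median log2 fold change was -0.01417. The authors' own scaling may place this median near 0, so the test cannot exclude scaling as a cause. A larger share of root in the seedlings may contribute. Of 21 other root markers, 19 were tested, with a median of 1.448 (0.22 to 2.22), and 11 were called higher and 1 lower. The interval was wholly positive. It also held the minimum rise set beforehand for this explanation, so the test did not decide. By group, 2 of 3 root cap genes (median 3.06), 4 of 4 root tip genes (2.15), 2 of 5 stele genes (0.06) and 3 of 7 cortex and uptake genes (0.30, with 1 lower) were called higher. The labels give whole seedlings, so an effect of the genotype on root growth and on root gene expression cannot be told apart here. A changed share of root could also move levels in the other lists, for which the root marker medians were given. That was not tested.

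Transcripts of seed maturation were seen in acc1-5, and this list and its test were chosen after some of its members had been seen. Of 12 tested members of the oil body and late embryogenesis list 4 rose and 2 fell. Of 2 tested members of the storage protein list 0 were called. In the authors' deposited table, the oleosin gene OLE2, the peroxiredoxin gene PER1 and the tonoplast channel gene TIP3;1 were called with 1.46, 1.70 and 0.581 FPKM in acc1-5 and listed at 0 in WT, whereas PAP85 and DOG1 fell. PAP85, counted in the oil body and late embryogenesis list, encodes a vicilin-like seed storage protein, so the 2 lists do not separate storage proteins cleanly. Seeds that had not germinated among the acc1-5 seedlings may be a source, and would bring storage protein transcripts in excess of oil body and late embryogenesis transcripts. The median FPKM in acc1-5 of the storage protein list minus that of the other list was -0.6846 (-1.39 to 2.92), an interval too wide to decide. PAP85 was counted in the other list there. Only 2 of the 8 members of the storage protein list were tested by the authors. CRA1, 1 of these 2, had 8.44 FPKM in acc1-5 and 0.000883 in WT, with q = 0.449 in the authors' deposited table.

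Extreme calls lay close to each other along the chromosomes; the test of neighbours was chosen after some neighbouring genes had been seen, while the tests of large segments and of families were written before their values were seen. Of 236 calls with an absolute log2 fold change of at least 3 or an FPKM of 0 in 1 genotype, 27.12% had another within 5 tested genes on either side, above the middle 95% of random draws of called genes, whose median was 11.4%. That may come from chromosome segments of another strain in 1 genotype, although the labels give Col-0 for both. Neighbouring genes of a family changing together are another possible source. The test of neighbours reads position only, so it cannot separate these explanations. Of the 236 extreme calls, 196 were higher in acc1-5. Of 41 neighbouring pairs, some of which share genes, 3 went opposite ways (7.32%, against 28.2% by chance), a count looked at afterwards. A large segment was not clear, as the most extreme calls in any 200 tested genes in a row were 10, against a median of 8 (7 to 11) in random draws. The test of families was too small to decide, because it read only symbols that end in a number and 0% of 2 such pairs shared a stem (a first run had counted locus identifiers as symbols and was corrected), while the pair HSP17.6II and HSP17.6A, of related genes, fell outside it.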
